A study of Mus musculus with 8 samples.

How the data were processed

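CD45-positive cells, the broad immune cell gate, were sorted by flow cytometry as live singlets from the cortex and hippocampus of mice heterozygous for 5XFAD and carrying human APOE knock-in alleles, per the labels. The 5XFAD line expresses human transgenes with familial Alzheimer's disease mutations and forms brain amyloid. Brains had been perfused, digested with collagenase D and cleared of myelin on Percoll before the sort, per the labels' protocols. RNA was read with the 10x Genomics 5′ v2 chemistry at 10 and 20 weeks, with the 3′ v2 chemistry at 96 weeks, and RNA with chromatin accessibility by the multiome assay at 60 weeks, per the labels. At 10 and 20 weeks the APOE2 (E2), APOE3 (E3) and APOE4 (E4) cells of an age carried different hashtag barcodes and were separated with Cell Ranger multi, per the labels' protocols, so those 3 libraries of an age come from 1 hashed pool. At 96 weeks there was 1 library of E3 and 1 of E4, and at 60 weeks 1 library of E4. How many mice entered a library is not given in the sources used here.

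The deposited matrices hold whole-number UMI counts per gene and cell for barcodes the authors had already called as cells, with no normalization in the values. Cell Ranger 6.1.1 and the build mm10 (GRCm38) are named per the submitters' processing notes, and Cell Ranger ARC 2.0.2 with an mm10 reference stands in the fragment file, per the file headers. The 96-week matrices list 27998 genes and the 10- and 20-week matrices 32285, so the annotations differ, and which Cell Ranger reference served the 96-week libraries is not given in the sources used here. Reads were counted against mouse genes, so the gene printed as Apoe is what the mouse reference caught of a locus exchanged for the human one. The fragment file gives the position and barcode of each unique fragment, as the authors deposited it. The hashtag counts were used to assign the allele of each young library and to leave out cells whose highest hashtag was another. The RNA matrix of the 60-week library was not analysed here. The fragment header names that library's age as 1 year where its label gives 60 weeks, and the label was used.

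Depth per library was read from the deposited matrices as total and median UMIs, and it is given with the results. In the hashed pools the hashtag of the stated allele was the highest of the 3 in 99.8% of cells or more in each library. The authors had separated the cells by these hashtags, so this share is no independent check of the allele. Cells with at least 1000 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored by the share of simulated pairs (2 per cell) among 50 neighbours. At 96 weeks the highest-scoring cells were removed at a rate of 0.8% per 1000 cells of the library. In the hashed pools the rate followed the cells of the whole pool and was lowered, since pairs with different hashtags were already gone. This removed 2.63% to 4.10% of the cells of the young libraries, and 5.43% of E3 and 1.87% of E4 at 96 weeks. The values of these filters, of the marker level and of the class score below were set after the data had been seen.

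Cells of 10 and 20 weeks were clustered together and those of 96 weeks apart, since chemistry and age coincide. The steps were log-normalized counts, 2000 variable genes, 30 principal components, a graph of 20 neighbours and Leiden clustering at resolution 1.0 with seed 1. Clusters were named from markers of 18 cell classes fixed before the data were examined, as was every comparison, gene list, size rule and the first group of settings tried below. A class needed at least 3 markers at 0.5 UMIs per 10000 and a score of at least 0.15, and a cluster stayed unnamed where its 10 leading genes went against the class. Clusters with over 95% of their cells from 1 library, and clusters of high UMIs that scored nearly as high for another class, were kept out of all classes. Both thresholds were set after the data had been seen, and the shares concerned are given. Microglia-like cells were clustered again and clusters named by leading state markers, apart from homeostatic clusters. That name went to clusters led by no other state, with homeostatic markers not lower than in the other cells. Every other state's mean log2 fold had to be below 0.5. Cells of homeostatic clusters are thus, by construction, also low in DAM, interferon, inflammatory, immediate early and heat shock genes. The share of the cluster led by Cst7, Igf1 and Lpl was chosen as a summary after the data had been seen.

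UMIs of microglia-like cells were summed per library and scaled by their total (CPM). Ratios were taken as log2 of CPM with a pseudocount of 0.5 UMIs and carry the exact conditional binomial interval at 95%. Shares of cells carry exact Clopper-Pearson intervals at 95%. With 1 library per allele and age there was no test, no p-value and no replicate check of any difference. A gene met the size rule when its log2 ratio was at least 0.5 in size with 1 sign in every pair compared, among genes with a mean of at least 20 CPM. The pairs were 3 ages for E4 against E3, 2 ages for E2 against E3 and for E4 against E2, and 3 alleles for 20 against 10 weeks. The 96-week libraries were not set against the younger ages. Named genes were, by rule, the 12 higher and the 12 lower genes with the largest smallest ratio over the pairs, and the 10 of each direction at 96 weeks alone. Ribosomal, mitochondrial, haemoglobin, immunoglobulin, T-cell receptor, Y-linked and Xist genes were left out of that ranking. Apoe, App and members of the fixed lists could be named too, and the list members quoted as examples were picked after their values had been seen.

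The lists were homeostatic, disease-associated (DAM), interferon, inflammatory, immediate early, heat shock, MHC class I and II, checkpoint, oxidative phosphorylation, glycolysis, cholesterol and lipid, lysosome and complement genes. Each list of at least 4 measured genes was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean CPM in 20 bins. Cycling and cytotoxic T-cell lists had too few genes measured in microglia-like cells for a median. Members were counted as higher or lower by the sign of the ratio among genes with a mean of at least 20 CPM in the pair.

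The ratio step was tested on simulated counts in 5 runs with 200 changed genes. At a fold of 2 the size rule found 92.3% of them for E4 against E3 (6499 genes), 92.5% for E2 against E3 (6696 genes), 92.2% for E4 against E2 (6707 genes) and 92.2% for 20 against 10 weeks (6718 genes). At a fold of 1.5 these shares were 58.9%, 69.4%, 64.3% and 62.3%, and at a fold of 4 they were 87.8%, 89.6%, 88.1% and 85.5%, because lowered genes passed under the CPM minimum. Of genes above that minimum, all were found at a fold of 4. The rule took up 0 unchanged genes in each comparison, and the intervals held the true ratio in 95.3%, 95.3%, 95.4% and 95.3% of genes. The simulated libraries differed by counting noise only, with no spread between mice, pools or libraries. These values therefore check the calculation and give no rate of false calls for the real libraries.

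For chromatin, fragments of the barcodes in the deposited multiome cell list were counted over the peaks of the deposited feature list. Nuclei with at least 1000 fragments and at least 20% of them in peaks were kept, and peaks seen in at least 20 nuclei were used. Nuclei were clustered after latent semantic indexing with 30 components. Classes were named from insertions in the gene body and 2000 bp around it, over the same markers, without the RNA of the same nuclei. Gene positions came from the RefSeq annotation of GRCm38.p6.

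The first group of other settings tried, fixed beforehand, held size factors by the median of ratios, totals without ribosomal and mitochondrial genes, doublets kept, stricter cell filters (2000 UMIs, 800 genes, 5% mitochondrial), microglia-like cells chosen per cell from 3 markers, cells thinned to 1000 UMIs, a minimum of 50 CPM or none, a log2 size of 1.0, each age left out, other clustering resolutions (0.6 and 1.6), clustering without immediate early and heat shock genes, a higher fragment minimum (5000) and promoter-distal peaks only. A second group, chosen after seeing the data, held adding the clusters found in 1 library, summing only cells of homeostatic clusters, leaving out genes within 20 Mb of Apoe, leaving out the 96-week cluster led by neutrophil genes, stricter cell filters for the states, and clustering without Ttr and the genes near Apoe. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.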

Results

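The libraries hold brain immune cells of 5XFAD mice in which the mouse Apoe gene had been exchanged for a human APOE allele. APOE carries lipids between cells, and its common alleles set the inherited risk of late-onset Alzheimer's disease, E4 raising it and E2 lowering it relative to E3. The design asks how the immune cells of an amyloid-bearing brain differ between the alleles and with age. At 10 weeks the deposited matrices held 3677 E2, 3575 E3 and 3912 E4 cells, and at 20 weeks 3251, 4421 and 5203. At 96 weeks they held 7108 E3 and 5190 E4 cells. A 60-week E4 library gave chromatin accessibility.

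Total UMIs were 14819560, 14962673 and 16808994 for E2, E3 and E4 at 10 weeks, 16094949, 19859966 and 23160589 at 20 weeks, and 30498669 and 10417424 for E3 and E4 at 96 weeks. Median UMIs per cell lay between 3511 and 4194 in 7 libraries and at 971.5 in 96-week E4. The minimum of 1000 UMIs removed 2666 cells (51.4%) of that library and 2.66% of 96-week E3. After filters and removal of 1.87% to 5.43% of cells as doublets, 3495, 3445 and 3755 cells remained at 10 weeks, 3120, 4260 and 4938 at 20 weeks, and 6421 and 2308 at 96 weeks. Each allele and age had 1 library, so no difference below has a replicate check, and the intervals in parentheses (95%) cover counting error only. In microglia-like cells Xist gave at most 2 UMIs in any library, and the Y-linked Ddx3y gave 47.5 to 104.5 CPM.

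Microglia-like cells, the resident macrophages of the brain, were the largest class in the young libraries. At 20 weeks they made up 78.7% (77.2 to 80.1) of E2, 79.5% (78.2 to 80.7) of E3 and 79.9% (78.7 to 81.0) of E4 cells. At 10 weeks the shares were 75.2% (73.7 to 76.6) in E2, 76.0% (74.5 to 77.4) in E3 and 63.8% (62.2 to 65.3) in E4. T-cell-like cells took 9.29% (8.38 to 10.3) of the 10-week E4 library, against 5.95% (5.19 to 6.79) in E2 and 5.60% (4.86 to 6.42) in E3. That order was not seen at 20 weeks, where T-cell-like cells took 6.83%, 6.22% and 4.84% of E2, E3 and E4. Monocyte-like cells at 10 weeks were 0.944%, 1.51% and 2.53% in E2, E3 and E4, and conventional dendritic-like cells 2.03%, 1.80% and 2.80%. B-cell-like cells ranged from 3.28% in 10-week E3 to 7.27% in 96-week E3. NK-cell-like cells were 2.40%, 2.93% and 3.81% at 10 weeks and between 1.67% and 1.79% at 20 weeks. Neutrophil-like cells were 0.887% of 10-week E2 and 2.41% of 10-week E3, and at 96 weeks 3.10% of E3 and 2.60% of E4. Border-macrophage-like cells took 1.25% to 2.84% of the young libraries. Under the stricter filter, which removes cells of few UMIs by construction, conventional dendritic-like cells were 0.210%, 0.0913% and 0.25% at 10 weeks, and B-cell-like cells 0.844% of E3 and 0.993% of E4 at 96 weeks. Neutrophil-like cells at 96 weeks were then 2.85% of E3 and 5.71% (4.21 to 7.54) of E4, the opposite order.

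Unnamed clusters held 4.21%, 4.44% and 9.48% of E2, E3 and E4 cells at 10 weeks, 3.40%, 2.72% and 3.04% at 20 weeks, and 6.42% and 5.63% of E3 and E4 at 96 weeks. These were 7.39%, 7.12% and 13.3% at 10 weeks under the stricter filter, and 2.38% and 3.03% at 96 weeks at the lower clustering resolution. In 10-week E4, 279 of them lay in a cluster led by Ace, Ear2, Treml4 and Cd300e. Clusters of high UMIs with markers of more than 1 class held 1.20% of 10-week E2 cells and under that elsewhere.

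At 96 weeks the microglia-like share was 76.9% (75.9 to 77.9) in E3 and 36.7% (34.7 to 38.7) in E4. A pair of clusters found almost only in the E4 library held 46.4% (44.4 to 48.5) of its cells and 0.0311% of E3 cells, and they were kept out of every class. A cluster mostly of 1 library may be that library and not a cell type, so the share at this age sets no order between the alleles. The gap in UMIs, 3951.5 against 971.5 per cell, stands beside it.

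The mix of microglial states differed between the ages sampled. Disease-associated microglia (DAM) are cells around amyloid that express Cst7, Igf1, Lpl and other lipid and lysosome genes. The cluster led by these genes held 13.9% (12.6 to 15.4) of E2, 8.30% (7.39 to 9.28) of E3 and 4.82% (4.17 to 5.53) of E4 microglia-like cells at 20 weeks. At 10 weeks it held 4 E2, 1 E3 and 1 E4 cells. Apoe and Ttr were among its leading genes and differ between the alleles. Clustered without Ttr and the genes within 20 Mb of Apoe, the 20-week shares were 13.2% (11.9 to 14.6), 7.74% (6.86 to 8.69) and 4.36% (3.75 to 5.05). At 96 weeks the shares were 4.96% (4.37 to 5.60) in E3 and 6.02% (4.52 to 7.84) in E4, then 8.42% and 10.0% without those genes, and 14.0% and 15.7% at the lower clustering resolution. Cells of this cluster had a median of 8264 UMIs, above the 3825 to 4137 of 20-week microglia-like cells.

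**Figure D1:**
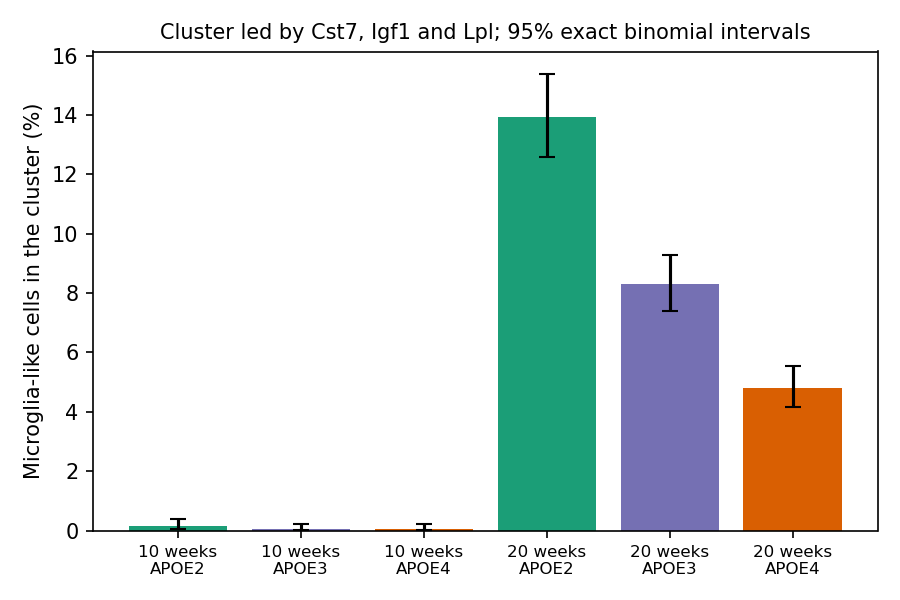
Percent of microglia-like cells (vertical axis, from 0) in the cluster led by Cst7, Igf1 and Lpl for the 6 libraries of 10 and 20 weeks, with exact 95% binomial intervals. The 20-week bars stand at 13.9% for E2, 8.30% for E3 and 4.82% for E4, and the 10-week bars are near 0.

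Homeostatic clusters, which express the resting markers P2ry12 and Tmem119, held 85.7%, 87.5% and 86.9% of E2, E3 and E4 microglia-like cells at 10 weeks. At 20 weeks they held 50.3%, 64.3% and 67.6%. Interferon clusters took 1.18%, 1.68% and 1.88% at 10 weeks and 4.28%, 4.28% and 4.26% at 20 weeks. Clusters led by inflammatory or immediate early genes held 6.66%, 4.39% and 4.76%, then 9.62%, 4.49% and 6.80%. All DAM-named clusters together, which include a second one with 4.77%, 3.69% and 5.76% at 20 weeks, held 1.86% (1.38 to 2.46), 2.03% (1.52 to 2.64) and 3.13% (2.47 to 3.91) at 10 weeks and 18.7%, 11.99% and 10.6% at 20 weeks. Cycling cells were 0.937%, 0.620% and 0.710% at 20 weeks. Unnamed state clusters held 4.30%, 4.17% and 2.96% at 10 weeks and 16.1%, 14.3% and 10.1% at 20 weeks. At 96 weeks homeostatic clusters held 53.1% of E3 and 44.7% of E4 microglia-like cells, heat shock clusters 18.2% and 10.3%, and unnamed clusters 3.89% and 17.9%. The unnamed cells lay in a cluster led by the neutrophil genes S100a8, S100a9, Ngp and Camp. At the lower resolution, clusters led by inflammatory or immediate early genes held 13.01%, 11.04% and 10.9% at 10 weeks and 27.6%, 21.5% and 21.9% at 20 weeks, and at 96 weeks homeostatic clusters held 23.1% and 15.2% and heat shock clusters 48.9% and 40.7%. All DAM-named clusters held 12.6%, 7.50% and 4.285% at 20 weeks at the higher resolution, and the unnamed clusters of that age 3.14%, 3.49% and 4.97% without immediate early and heat shock genes. After thinning, the 20-week shares were 2.36%, 3.13% and 2.99% for interferon and 0.530%, 0.325% and 0.583% for cycling cells, and the 96-week unnamed share was 37.3% and 48.4%.

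Between 10 and 20 weeks, DAM genes were higher in microglia-like cells of all 3 alleles, and by most in E2. Cst7, a cysteine protease inhibitor, had a log2 ratio of 5.75 (5.49 to 6.03) in E2, 4.81 (4.60 to 5.03) in E3 and 3.82 (3.62 to 4.04) in E4, with 680, 546 and 318 CPM at 20 weeks. The growth factor gene Igf1 stood at 6.15 (5.33 to 7.28), 5.22 (4.36 to 6.43) and 4.51 (3.72 to 5.58). Lpl, which encodes lipoprotein lipase, stood at 3.36, 2.98 and 2.74. Apoe, counted against the mouse reference, stood at 4.09 (3.90 to 4.29), 2.34 (2.18 to 2.51) and 1.04 (0.87 to 1.21). Ddit4, an inhibitor of mTOR signalling, was lower, at −3.59 (−3.85 to −3.34), −1.76 (−2.01 to −1.53) and −2.74 (−2.92 to −2.56), as were Fkbp5, which binds steroid receptor complexes, at −2.16, −1.50 and −2.03, and the clock gene Per1, at −1.81, −1.15 and −1.20.

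The size rule was met by 100 higher and 55 lower genes of 6718 measured, with 1 sign in all 3 alleles. That split was 116 and 46 with size factors, and 125 and 47 without ribosomal and mitochondrial genes in the totals. It was 78 and 31 after thinning, and 58 and 22 in cells of homeostatic clusters alone. Within 1 allele, 263 genes were higher and 401 lower by the same size in E2, 168 and 148 in E3, and 175 and 89 in E4. Other named genes that were higher, given for E2, E3 and E4 in turn, were Baiap2l2 (6.48, 6.19 and 5.76), the interferon gene Ifi27l2a (2.86, 3.42 and 2.56), Ank (3.35, 2.70 and 2.24), the receptor kinase Axl (3.63, 4.21 and 2.17), Lilrb4a (3.06, 2.58 and 1.92), Myo1e (2.11, 2.02 and 1.90), Capg (1.96, 1.77 and 1.77) and Fosb (1.89, 1.76 and 2.14). Ttr, the transthyretin gene of the choroid plexus, was at 9.45 (7.56 to 15.34), 1.84 and 8.08 over only 1, 12 and 2 UMIs at 10 weeks. Other named genes that were lower were Gm43305 (−1.81, −1.20 and −1.76), Ccnd3 (−1.35, −0.98 and −1.17), Tsc22d3 (−2.14, −0.78 and −1.19), Filip1l (−1.32, −0.85 and −0.75), Sult1a1 (−1.12, −0.72 and −1.005) and E430024P14Rik (−0.97, −0.75 and −1.04). Tmc7, Ahsa2 and Dnaja1 lay between −0.98 and −0.72 in all 3 alleles.

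The DAM list had a median log2 ratio of 1.25 in E2, 0.74 in E3 and 0.27 in E4, above 99.99% of random lists or more, with all 16, 14 and 13 measured members higher. An example is Csf1, a microglial growth factor gene (2.98, 2.10 and 1.29). Homeostatic genes had medians of −0.48, −0.26 and −0.12 (percentiles 0.04, 0.59 and 16.6), with Tmem119 at −0.78, −0.56 and −0.35. Interferon genes stood at 1.14, 1.16 and 0.90, with Ifitm3 at 2.21, 2.05 and 1.63. MHC class II genes, which present antigen to helper T cells, stood at 0.63, 0.78 and 0.47, with Cd74 at 1.25, 1.67 and 0.83. Inflammatory genes had medians of 0.68, 0.37 and 0.57, with Ccl3 at 2.45, 1.79 and 1.45, and immediate early genes of 0.57, 0.48 and 0.60. MHC class I genes stood at 0.39, 0.19 and 0.088, oxidative phosphorylation genes at 0.23, 0.20 and 0.13, and glycolysis genes at 0.49, 0.20 and 0.064. The lysosome list stood at 0.21, 0.073 and −0.050, with the lysozyme gene Lyz2 at 2.21, 1.39 and 0.75. Checkpoint genes stood at −0.23, −0.27 and −0.25 (percentiles 19.3, 4.23 and 1.59), outside the central 95% of random lists in E4. Heat shock (−0.22, 0.072 and −0.017), cholesterol and lipid (0.043, 0.045 and 0.059) and complement genes (−0.067, −0.16 and −0.12) lay inside that range in all 3 alleles, and the median of all genes was −0.079.

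**Figure D2:**
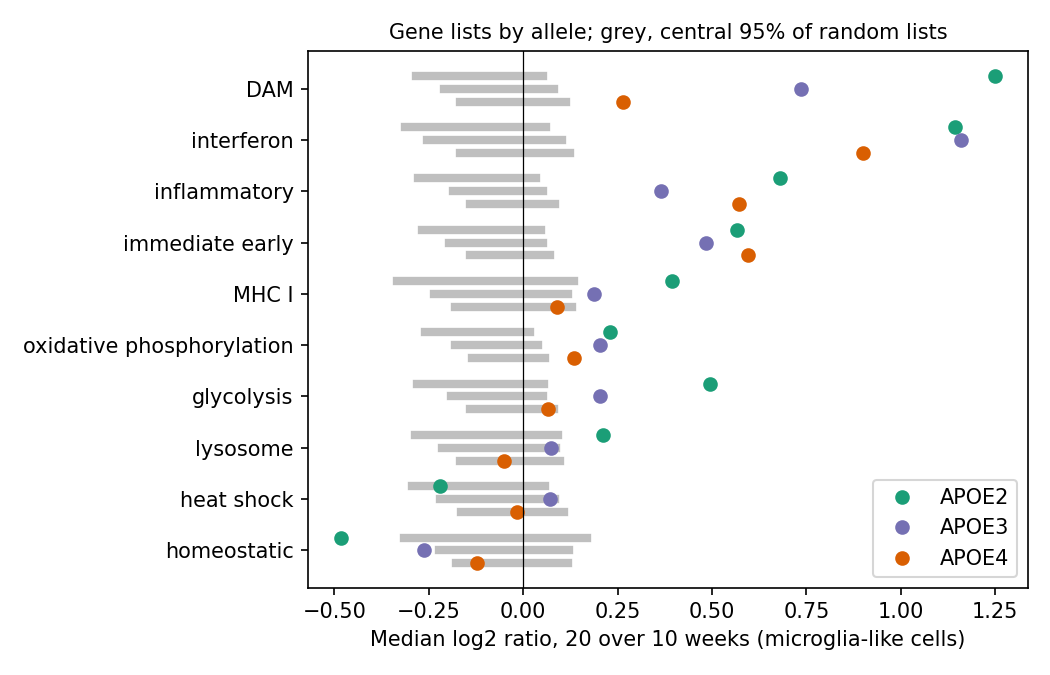
Median log2 ratio of CPM at 20 over 10 weeks (horizontal axis) for gene lists in E2, E3 and E4 microglia-like cells, as points, with the central 95% of random lists of the same size in grey. The MHC class II, checkpoint, cholesterol and lipid, and complement lists are not drawn. The DAM medians of 1.25, 0.74 and 0.27 and the interferon medians of 1.14, 1.16 and 0.90 lie to the right of it.

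Other RNA moved between these libraries too. Haemoglobin in microglia-like cells was 540, 252 and 356 CPM at 10 weeks and 2.10, 58.7 and 18.5 at 20 weeks, neutrophil markers 230, 235 and 232, then 269, 280 and 281, plasmacytoid dendritic cell markers 13.1, 9.93 and 10.2, then 66.2, 53.0 and 39.2, T-cell markers 64.3, 49.5 and 68.0, then 32.0, 33.5 and 49.1, and ribosomal protein genes 54900, 63780 and 58710, then 85640, 83170 and 69040. The largest clusters were 1 and 2 at 10 weeks and cluster 0 at 20 weeks, which held 38.3%, 38.1% and 45.6% of E2, E3 and E4 microglia-like cells. Each age was 1 hashed pool, so age and run cannot be told apart. In cells of homeostatic clusters alone several medians changed sign. There DAM genes stood at −0.053 in E3 and −0.090 in E4, oxidative phosphorylation genes at −0.067, −0.084 and −0.079, glycolysis genes at −0.085 in E2 and −0.20 in E3, lysosome genes at −0.064 in E2, homeostatic genes at 0.074 and MHC class I genes at −0.12 in E3, and Axl at −1.03 in E4.

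Ranked by the smaller of the ratios at 10 and 20 weeks, E2 and E3 microglia-like cells differed most in the C5a receptor genes. C5ar2, a receptor for the complement fragment C5a (chromosome 7, 16234587 to 16244154), was higher in E2 by a log2 ratio of 2.67 (2.32 to 3.05) at 10 weeks and 2.65 (2.32 to 2.996) at 20 weeks, at 50.5 against 7.90 and 37.7 against 6.001 CPM. Its neighbour C5ar1 (16246743 to 16259540) was higher by 1.25 (1.12 to 1.39) and 1.51 (1.39 to 1.63). Bcl2a1d, of a family of near-identical cell survival genes among which reads can be split, was lower in E2 by −3.30 (−3.75 to −2.90) and −1.19 (−1.46 to −0.93). Gmfg, which remodels actin (chromosome 7, 28437469 to 28448230), was lower by −1.04 (−1.17 to −0.92) and −1.01 (−1.12 to −0.90). The inhibitory receptor gene Pirb (chromosome 7, 3712505 to 3720382), also of a family of close copies, was lower by −1.23 (−1.46 to −1.005) and −0.95 (−1.19 to −0.71).

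The size rule was met by 18 genes higher and 12 lower in E2 at both ages, of 6696 measured. Of these 30 genes, 9 lie within 20 Mb of Apoe (chromosome 7, 19696244 to 19701310), among 158 such genes of 6623 with a position. They are Myadm, Pirb, Ccdc106, Meis3, C5ar2, C5ar1, Gmfg, Zfp30 and Fxyd5. Other named genes that were higher in E2, at 10 and 20 weeks, were Myadm (0.72 and 0.70), the growth arrest factor Klf4 (0.83 and 0.70), Tmem52 (0.73 and 0.78), Lrrc75a (0.82 and 0.66), Dusp1 (0.70 and 0.66), Tuba1c (0.70 and 0.63), Ier2 (0.62 and 0.69), Grap (0.61 and 0.68), Fos (0.58 and 0.57) and Baiap2l2 (0.68, −0.88 to 2.47, and 0.97). Lower were Ccnb1ip1 (−1.32 and −1.05), the chemokine receptor gene Ccr1 (−1.21 and −0.96), Pttg1 (−1.21 and −0.86), Rnase6 (−0.69 and −0.76), Zfp30 (−0.65 and −0.73), Ang (−0.82 and −0.58), Cdk5rap1 (−0.86 and −0.57), Ccdc106 (−0.59 and −0.56) and Crtap (−1.02 and −0.52). Apoe was lower in E2 at 10 weeks, at −0.60 (−0.85 to −0.36), and higher at 20 weeks, at 1.14 (1.07 to 1.21), from 24.4 against 37.1 and 416 against 189 CPM.

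**Figure D3:**
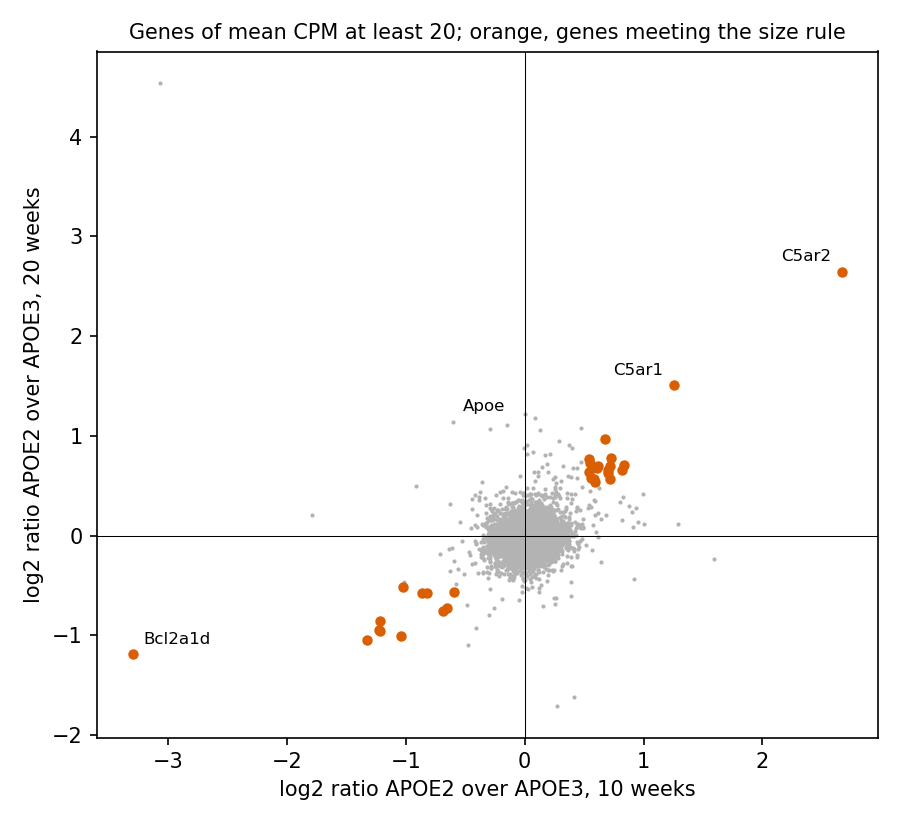
Log2 ratio of E2 over E3 in microglia-like cells at 10 weeks (horizontal axis) and at 20 weeks (vertical axis), 1 point per gene with a mean of at least 20 CPM, genes that met the size rule in orange. C5ar2 lies at 2.67 and 2.65, C5ar1 at 1.25 and 1.51, and Bcl2a1d at −3.30 and −1.19, and Apoe lies on opposite sides of 0 at −0.60 and 1.14.

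Immediate early genes, which respond within minutes to stimulation and to tissue handling, were higher in E2 at both ages. Their medians were 0.34, with 18 members higher and 1 lower, and 0.43, with 21 higher and 0 lower, each above all but a few of the random lists. At 20 weeks E2 was higher than E3 in DAM genes (0.27; 17 higher, 0 lower), inflammatory genes (0.47; 14 higher, 1 lower), MHC class I genes (0.22; 7 higher, 2 lower), interferon genes (0.12; 8 higher, 3 lower) and glycolysis genes (0.12; 10 higher, 3 lower). Examples are Csf1 (0.88), Igf1 (1.06), Lpl (0.70), Ccl4 (1.11) and Tnf (1.07). Homeostatic genes were lower in E2 (−0.18; 1 higher, 11 lower), as were heat shock genes (−0.24; 2 higher, 9 lower), with Hspa1a at −1.62 and Hspa1b at −1.71. At 10 weeks the DAM (−0.11), inflammatory (−0.089), MHC class I (−0.066), glycolysis (−0.18), lysosome (−0.11) and heat shock (−0.11) medians were below 0, with percentiles of 1.65 or less, and interferon stood at −0.057 (percentile 11.2). The lysosome list stood at 0.068 at 20 weeks, oxidative phosphorylation at 0.0070 and 0.047, homeostatic genes at 0.048 at 10 weeks, and MHC class II at −0.0061 at 20 weeks. Checkpoint (0.026 and −0.052), cholesterol and lipid (−0.026 and 0.031) and complement (−0.051 and 0.027) lists lay near 0. In cells of homeostatic clusters alone the 20-week medians were −0.037 for DAM, −0.029 for glycolysis and 0.015 for homeostatic genes, the 10-week immediate early median was −0.024, and Ier2 stood at −0.091 and Baiap2l2 at −2.29 at 10 weeks. With microglia chosen per cell the 10-week inflammatory median was 0.0060.

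E4 and E3 microglia-like cells shared few differences across the 3 ages. Genes that met the size rule at 10, 20 and 96 weeks were Myadm and Tuba1c, higher in E4, and Pirb and Cdk5rap1, lower, of 6499 measured. Myadm, a myeloid membrane protein gene (chromosome 7, 3289038 to 3299355), stood at 0.68 (0.54 to 0.81), 0.86 (0.74 to 0.98) and 0.70 (0.32 to 1.05), and the tubulin gene Tuba1c at 0.51 (0.21 to 0.81), 0.54 (0.35 to 0.73) and 0.68 (0.11 to 1.19). Pirb stood at −0.62 (−0.83 to −0.42), −0.72 (−0.93 to −0.52) and −0.84 (−1.21 to −0.51), and Cdk5rap1 at −0.61 (−0.84 to −0.39), −1.65 (−1.94 to −1.37) and −0.58 (−0.99 to −0.22). C5ar1 was higher at each age, at 0.93 (0.79 to 1.07), 1.77 (1.66 to 1.89) and 0.46 (0.23 to 0.69). All genes of this paragraph up to here had the same sign in E2 against E3 at 10 and 20 weeks. E3 is the library that both comparisons share. At 10 weeks Myadm stood at 130, 79.3 and 127 CPM and Pirb at 24.5, 57.5 and 37.3 in E2, E3 and E4. For these genes a difference of the E3 library cannot be told apart from an effect of E4. Apoe did not differ beyond counting error at 10 weeks, at 0.19 (−0.02 to 0.41), and was lower in E4 at 20 weeks, at −1.12 (−1.21 to −1.02), and at 96 weeks, at −1.21 (−1.29 to −1.13).

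The split of 2 higher and 2 lower genes became 1 and 2 with size factors, and 3 and 2 without ribosomal and mitochondrial genes in the totals. It was 9 and 2 with microglia chosen per cell. After thinning it was 3 and 0, where Pirb stood at −0.42 at 10 weeks and Cdk5rap1 at −0.48 at 96 weeks. Other genes with 1 sign at the 3 ages and named by rule were Ddit4 (1.40, 0.43 and 1.01), Per1 (0.46, 0.41 and 0.46), Kdm6b (0.29, 0.70 and 0.40), Csrnp1 (0.41, 0.38 and 0.34), Cdh23 (0.32, 0.38 and 0.46), Gcnt2 (0.44, 0.31 and 0.32), Mboat7 (0.30, 0.37 and 0.28), E2f3 (0.35, 0.31 and 0.29) and Gm32849 (0.38, 0.37 and 0.45). Lower in E4 were St8sia6 (−0.55, −1.62 and −0.45), Gm26740 (−0.78, −1.22 and −0.24), Gm20186 (−0.95, −0.24 and −0.52), Igfbp4 (−0.32, −0.49 and −0.33), Tmem160 (−0.29, −0.58 and −0.31), Hist4h4 (−0.68, −0.46 and −0.24), Ccdc106 (−0.44, −0.26 and −0.24), Ermard (−0.32, −0.36 and −0.37), Gmfg (−0.33, −0.29 and −0.28) and Ppcdc (−0.27, −0.38 and −0.32). The interval included 0 for E2f3, Igfbp4, Hist4h4, Ccdc106 and Gm26740 at 96 weeks, Gm20186 at 20 weeks, Kdm6b at 10 weeks and Gm32849 at 10 and 20 weeks. With microglia chosen per cell, E2f3 stood at −0.044 and Gmfg at 0.12 at 96 weeks, and after thinning Ccdc106 stood at 0.11 at 96 weeks and Gm20186 at 0.15 at 20 weeks.

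At 20 weeks DAM genes were lower in E4 than in E3, with a median of −0.33, 0 members higher and 15 lower, below all random lists. Cst7 at −0.78 and Axl at −1.03 were the members with a log2 ratio of at least 0.5 in size. Glycolysis (−0.18; 2 higher, 12 lower), oxidative phosphorylation (−0.082; 2 higher, 16 lower) and lysosome genes (−0.094; 3 higher, 12 lower) were lower as well. Homeostatic genes (0.14; 12 higher, 0 lower), immediate early genes (0.22; 20 higher, 0 lower) and inflammatory genes (0.12; 11 higher, 3 lower) were higher in E4. Interferon (0.071), cholesterol and lipid (0.043), complement (0.036), checkpoint (0.087), heat shock (0.0069), MHC class I (0.0039) and MHC class II genes (−0.010) lay near 0. At 10 weeks the heat shock list was at 0.10 (7 higher, 4 lower; percentile 99.9) and the interferon list at 0.13 (6 higher, 1 lower; percentile 98.0), DAM at 0.038, MHC class I at 0.054, checkpoint at 0.078, inflammatory at 0.049, immediate early at −0.0044 and homeostatic at 0.0094, and the remaining lists lay between −0.032 and 0.031. In cells of homeostatic clusters alone the 20-week lysosome median was 0.033.

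At 96 weeks, genes of antigen presentation and interferon response were higher in E4 than in E3 microglia-like cells. MHC class II genes had a median of 0.40 (4 higher, 2 lower), with Cd74 at 0.76, H2-Eb1 at 0.80 and H2-DMa at −0.26. The cluster led by MHC class II genes was not larger in E4, at 1.42% (0.73 to 2.46) against 1.62% (1.29 to 2.01) in E3. B-cell markers were 48.1 CPM in E4 and 39.7 in E3 microglia-like cells, and conventional dendritic cell markers 256 in both. The part of RNA from other cell types in these lists was not tested. Interferon genes stood at 0.22 (9 higher, 1 lower), with Ifitm3 at 0.75, and MHC class I genes at 0.16 (6 higher, 3 lower). Heat shock genes were lower, at −0.15 (1 higher, 11 lower), with Hspa1a at −0.54 and Hspb1 at −0.50. The 10 highest genes were Wfdc17 (2.41, 2.07 to 2.75), the neutrophil genes S100a8 (1.64), S100a9 (1.56) and Retnlg (1.41), Tcap (1.25), S100a6 (1.25), the DAM gene Spp1 (1.10), the chemokine gene Ccl5 (1.03), Ddit4 (1.01) and Gm43936 (0.98). The 10 lowest were Gm10709 (−1.28), the lysosomal sulfatase gene Arsb (−1.26), Apoe (−1.21), Ccr1 (−1.02), Pon2 (−0.85), Pirb (−0.84), Ppm1b (−0.74), D6Wsu163e (−0.70), Hspa1b (−0.70) and Gm10762 (−0.66). DAM (0.085; 11 higher, 6 lower), inflammatory (0.12; 11 higher, 6 lower), cholesterol and lipid (0.085) and homeostatic genes (−0.089; 5 higher, 7 lower) differed less, and immediate early (0.033), oxidative phosphorylation (0.030), glycolysis (0.0080), complement (−0.013), lysosome (−0.027) and checkpoint genes (−0.061) lay near 0.

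At that age 847 E4 cells with 3120975 UMIs stood against 4939 E3 cells with 20192238 UMIs, held mainly by clusters 0, 5 and 2 in E4 and 0, 1 and 2 in E3. Neutrophil markers were 832 CPM in E4 and 467 in E3 microglia-like cells, monocyte markers 39.4 and 20.4, border macrophage markers 10.6 and 4.41, NK-cell markers 9.61 and 4.06, and haemoglobin 1464 and 179, against ribosomal protein genes at 71560 and 64430. Of the neutrophil markers, Csf3r alone gave 341 CPM in E4 microglia-like cells against 307 in the whole E4 library. It does not set neutrophils apart here, so that sum is not all RNA of neutrophils. The cluster led by S100a8, S100a9, Ngp and Camp held 152 (17.9%) of these E4 cells and 192 (3.89%) of the E3 cells. Without it, S100a8 stood at 1.08 (0.89 to 1.26), S100a9 at 1.12 (0.96 to 1.26), Retnlg at 1.10, S100a6 at 0.82 and Ccl5 at 0.71, MHC class II genes at 0.35 and interferon genes at 0.26. In cells of homeostatic clusters alone Spp1 stood at 0.0076 (−2.10 to 1.36), Tcap at −1.03 (−6.95 to 1.06), interferon genes at 0.12, MHC class I genes at 0.034 and DAM genes at −0.16, and the DAM median was −0.026 after thinning.

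E4 and E2 microglia-like cells lay furthest apart at 20 weeks, where the DAM list had a median of −0.64 for E4 over E2, with 0 members higher and 17 lower. Cst7 was at −1.09, Itgax at −1.04, Csf1 at −1.24 and Axl at −1.45, and Apoe at −2.26 (−2.34 to −2.17). Glycolysis (−0.34; 1 higher, 12 lower), inflammatory (−0.31; 4 higher, 11 lower), MHC class I (−0.19), MHC class II (−0.16), oxidative phosphorylation (−0.17; 2 higher, 16 lower), lysosome (−0.16) and interferon genes (−0.085) were lower in E4 too. Homeostatic genes were higher in E4, with a median of 0.36 (12 higher, 0 lower), and heat shock genes, with 0.34 (10 higher, 2 lower) and Hspa1b at 1.38. Immediate early genes were lower in E4 at both ages, at −0.33 (1 higher, 18 lower) and −0.32 (3 higher, 18 lower). The 20-week signs of 2 lists turned, lysosome genes standing at 0.072 in cells of homeostatic clusters alone and MHC class II genes at 0.13 with microglia chosen per cell.

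At 10 weeks several of these lists stood on the other side of 0 for E4 over E2, with DAM at 0.13 (9 higher, 2 lower), interferon at 0.20, glycolysis at 0.14 (13 higher, 1 lower), lysosome at 0.12 (13 higher, 2 lower), MHC class I at 0.10 and inflammatory at 0.073. Heat shock stood at 0.20 (9 higher, 2 lower), checkpoint at 0.11 and 0.16, cholesterol and lipid at 0.038 and −0.014, complement at 0.065 and 0.013, and at 10 weeks homeostatic genes at −0.022 and oxidative phosphorylation at −0.012. The size rule was met by 9 genes higher and 9 lower in E4 at both ages, of 6707 measured. That split was 9 and 14 after thinning, and 5 and 14 in cells of homeostatic clusters alone. Named genes that were higher, at 10 and 20 weeks, were Bcl2a1d (2.79 and 1.61), Ccr1 (0.72 and 1.24), the interferon-induced chemokine gene Cxcl10 (1.30 and 0.62), Irgm2 (0.54 and 0.62), Fcrl1 (0.71 and 1.38), Ccnb1ip1 (1.24 and 0.80), Hjurp (0.88 and 0.86), Gmfg (0.72 and 0.72), Ang (0.73 and 0.53), Rnase6 (0.59 and 0.48), B4galnt1 (0.63 and 0.46) and Ahsa2 (0.49 and 0.47). Lower were the protease gene Adamts1, at −1.10 (−1.29 to −0.91) and −1.12 (−1.20 to −1.04), and the growth factor signalling inhibitor Spry1, at −1.12 (−1.36 to −0.89) and −1.03 (−1.22 to −0.84). Gm46620 (−1.25 and −1.86), Gm42031 (−0.99 and −0.93), Gm26740 (−0.80 and −1.11), Myo1e (−0.74 and −0.95), Lrrc75a (−0.73 and −0.64), Capg (−0.63 and −0.83), Baiap2l2 (−0.58, −2.37 to 0.98, and −1.30), Ier2 (−0.50 and −0.45), Fxyd5 (−0.46 and −0.45) and Lpl (−0.44 and −1.06) were lower as well. Apoe was higher in E4 at 10 weeks, at 0.80 (0.56 to 1.04). In cells of homeostatic clusters alone the 10-week inflammatory median was −0.022, and Baiap2l2 stood at 1.67 at 10 weeks and Fxyd5 at 0.17 at 20 weeks.

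App, the mouse amyloid precursor gene, was near equal in the young libraries, at 215, 220 and 217 CPM in E2, E3 and E4 at 10 weeks and 214, 209 and 221 at 20 weeks. Median UMIs of microglia-like cells were 3439.5, 3441 and 3498 at 10 weeks and 4137, 3891 and 3825 at 20 weeks. Ribosomal protein genes were lower in 20-week E4, at 69040 CPM, than in E2 and E3, at 85640 and 83170, and haemoglobin was 2.10, 58.7 and 18.5 CPM in 20-week E2, E3 and E4. Astrocyte markers stood at 170, 143 and 181 CPM at 10 weeks and 113, 106 and 124 at 20 weeks.

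Chromatin of the 60-week E4 library showed an accessible DAM programme in part of the microglia-like nuclei. A cluster of 358 nuclei had more insertions over DAM loci than the other microglia-like nuclei, with a median log2 ratio of 0.42 and 18 of 20 loci higher, and fewer over homeostatic loci, with a median of −0.30 and 0 of 12 higher. Insertions over Igf1, scaled to the cluster's total as CPM, were 56.1 (53.2 to 59.3) in that cluster and 7.78 (7.01 to 8.62) in the largest cluster of 847 nuclei. Lpl stood at 36.5 against 8.95, Cst7 at 31.0 against 10.9 and Clec7a at 31.6 against 11.6, while Tmem119 stood at 43.6 against 79.2 and P2ry12 at 131 against 175. Igf1 is among the genes that define the cluster, so its value describes the cluster and compares no groups.

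The library held 124214394 fragments, 94.1% of them in 5335 listed barcodes and on the autosomes and sex chromosomes. The filters kept 5111 nuclei with a median of 23040 fragments, 71.2% in peaks and 48.8% shorter than a nucleosome. Microglia-like nuclei made up 53.4% (52.0 to 54.7), T-cell-like 11.3%, neutrophil-like 7.02%, B-cell-like 4.93%, monocyte-like 2.43% and border-macrophage-like 1.25%, and 18.6% were unnamed. The unnamed nuclei include a cluster of 690 with a median of 3804 fragments whose highest score was for microglia. B-cell-like nuclei were 1.02% at the higher clustering resolution and 1.04% with promoter-distal peaks, and at the higher fragment minimum microglia-like nuclei were 70.1% and unnamed nuclei 3.97%. Of the 126085 peaks on the autosomes and the X chromosome, 101577 (80.6%) lay over 2000 bp from either end of a protein-coding gene, the promoter-distal set. The main clustering used 125893 peaks, those seen in enough nuclei. Over mouse Apoe, the 6 bins of 250 bp from 19696994 to 19698493 of chromosome 7 held 2 insertions in all, and the bins on either side held 28 and 41.

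**Figure D4:**
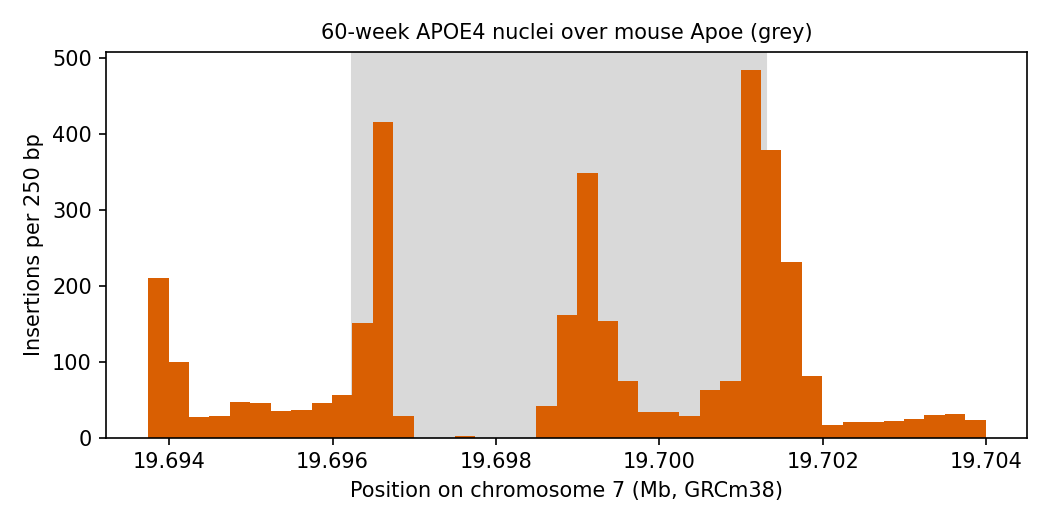
Insertions per 250 bp bin (vertical axis) along chromosome 7 of GRCm38 around mouse Apoe (horizontal axis, Mb) in the 60-week E4 library, with the gene in grey. The stretch from 19696994 to 19698493 holds 2 insertions between bins with 28 and 41.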

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

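All tests of the clusters found in 1 library were chosen after the result was seen. The gene lists below drew attention because their medians lay outside the central 95% of random lists on opposite sides at different ages, and none of these differences was tested, since each age and allele had 1 library. DAM genes in microglia-like cells had a median log2 ratio of E2 over E3 of −0.11 at 10 weeks and 0.27 at 20 weeks, of E4 over E2 of 0.13 and −0.64, and of E4 over E3 of −0.33 at 20 weeks and 0.085 at 96 weeks. Inflammatory genes stood at −0.089 and 0.47 for E2 over E3 and at 0.073 and −0.31 for E4 over E2, at 10 and 20 weeks in turn. MHC class I genes stood at −0.066 and 0.22 and at 0.10 and −0.19, and glycolysis genes at −0.18 and 0.12 and at 0.14 and −0.34. For E4 over E2, interferon genes stood at 0.20 and −0.085 and lysosome genes at 0.12 and −0.16. Heat shock genes stood at 0.10 at 10 weeks and −0.15 at 96 weeks for E4 over E3. The 96-week values come from another chemistry. Some of these signs turned under other settings, as given below. For E4 over E3 this held for DAM genes at 96 weeks after thinning and in homeostatic clusters alone. For E2 over E3 it held for DAM and glycolysis genes at 20 weeks in homeostatic clusters alone, and for inflammatory genes at 10 weeks with microglia chosen per cell. For E4 over E2 it held for inflammatory genes at 10 weeks after thinning, and in homeostatic clusters alone for these and for lysosome genes at 20 weeks.

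In the 96-week E4 library, 46.4% of the cells kept lay in a pair of clusters with almost no E3 cells, which entered no comparison. The clusters held 723 cells at a median of 1320 UMIs and 349 at 5287, and mitochondrial RNA was 6.102% and 7.94% of their UMIs against 2.08% in microglia-like cells. The median of 5287 lies above the 3600 of the microglia-like cells, which argues against low UMIs as the whole cause for the cluster of 349 cells. For the 723 cells at 1320 UMIs, below that 3600, low UMIs stay open. In these clusters 44 markers of 9 other cell classes had a median log2 ratio of 3.74 over the library's microglia-like cells. The quartiles were 2.14 and 4.26. Markers with few UMIs in these clusters were left out of the 44, a choice that favours high values. For the markers kept, the values argue against a microglial state free of RNA of other cell types. Microglia markers had a median of −0.83 over those cells. Microglia that carry RNA of other cell types would give both values, so this test cannot exclude them. A candidate explanation is RNA of all cell types mixed in these droplets. The 44 markers had a median ratio of −0.44 to the cells kept of the library outside these clusters, with quartiles of −0.74 and −0.19. The same choice of markers raises this value, so it does not decide the question. Age, allele and a loss of cell quality in this library remain untested.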

How the results depend on the processing

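Tests with cells of homeostatic clusters only, with the clusters found in 1 library added, without genes near Apoe, without the 96-week cluster led by neutrophil genes, clustered without Ttr and the genes near Apoe, and with stricter filters for the states were chosen after the result was seen. The 20 against 10 week ratios form 3 pairs matched by allele, and a paired or additive fit over the 6 young libraries, with alleles in the place of replicates, was not run. Over the alternatives, 79 main results stayed within 1.5 times a count or inside the interval of a share and 36 moved, 810 list medians stayed, 140 moved and 22 that lay outside the random range changed sign, 635 named genes stayed, 74 moved and 11 changed sign, and 427 other shares stayed and 260 moved. Size factors, totals without ribosomal and mitochondrial genes, the higher resolution, promoter-distal peaks, leaving out the 96-week cluster led by neutrophil genes, and clustering without Ttr and the genes near Apoe moved no main result, which are the counts, the microglia-like shares and the 20-week shares led by DAM genes. Without Ttr and the genes near Apoe the 96-week DAM-led share was 8.42% in E3 and 10.0% in E4, and B-cell-like nuclei were 1.04% with promoter-distal peaks. Depth limits 96-week E4, with 971.5 UMIs per cell.

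The genes that met the size rule, 4 for E4 against E3, 30 for E2 against E3, 18 for E4 against E2 and 155 for 20 against 10 weeks, became 1, 11, 6 and 91 at 50 CPM, 0, 5, 4 and 36 at a log2 size of 1.0, and 369, 1270, 1223 and 1563 with no minimum, where genes of few UMIs enter by construction. For E4 against E3 the count was 11 without 96 weeks, 8 without 10 weeks, 12 without 20 weeks, 11 with microglia chosen per cell and 2 without genes near Apoe. With homeostatic clusters only it was 80 for 20 against 10 weeks (58 higher and 22 lower), and 47 list medians, not 75, lay outside the random range. The microglia-like share under the stricter filter was 80.2%, 80.8% and 81.2% for E2, E3 and E4 at 20 weeks, and 85.2% and 76.3% for E3 and E4 at 96 weeks. The 20-week share led by DAM genes was 17.5%, 9.42% and 6.06% at the lower resolution and 18.1%, 9.65% and 6.30% under the stricter filter. It was 16.7% in E2 and 5.65% in E4 without immediate early and heat shock genes, 15.8% and 5.92% with doublets kept, and 12.2% in E2 after thinning. The microglia-like share of nuclei was 70.1% at the higher fragment minimum. Apart from the genes of few UMIs, the cause was not tested.

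Signs of named genes reversed as follows, each as the log2 ratio in the pair where its size was smallest, and the cause was not tested. For E4 against E3, E2f3 stood at −0.044 and Gmfg at 0.12 with microglia chosen per cell, E2f3 at −0.013 and Gmfg at 0.12 with the clusters of 1 library added, and Ccdc106 at 0.11 and Gm20186 at 0.15 after thinning. With homeostatic clusters only, Baiap2l2 stood at −2.29 for E2 against E3 and 1.67 for E4 against E2, Ier2 at −0.091 for E2 against E3, Fxyd5 at 0.17 for E4 against E2 and Axl at −1.03 for 20 against 10 weeks.

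Signs of list medians reversed as follows, and the cause was not tested. With microglia chosen per cell, inflammatory genes stood at 0.0060 for E2 over E3 at 10 weeks and MHC class II genes at 0.13 for E4 over E2 at 20 weeks. After thinning, DAM genes stood at −0.026 for E4 over E3 at 96 weeks and inflammatory genes at −0.014 for E4 over E2 at 10 weeks. The setting with homeostatic clusters only leaves out, by construction, clusters high in DAM, inflammatory, immediate early or other state genes. There DAM genes stood at −0.16 for E4 over E3 at 96 weeks, −0.037 for E2 over E3 at 20 weeks, and −0.053 in E3 and −0.090 in E4 for 20 over 10 weeks. Homeostatic genes stood at 0.015 for E2 over E3 at 20 weeks and 0.074 in E3 for 20 over 10 weeks. Immediate early genes stood at −0.024 for E2 over E3 and inflammatory genes at −0.022 for E4 over E2, both at 10 weeks. Lysosome genes stood at 0.033 for E4 over E3 and 0.072 for E4 over E2 at 20 weeks, and −0.064 in E2 for 20 over 10 weeks. Glycolysis genes stood at −0.029 for E2 over E3 at 20 weeks, and for 20 over 10 weeks at −0.085 in E2 and −0.20 in E3, oxidative phosphorylation genes at −0.067, −0.084 and −0.079 in E2, E3 and E4, and MHC class I genes at −0.12 in E3.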

Other observations

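The test of sequence around Apoe in other cell types was set before its result was seen, and all other tests here were chosen after the result was seen. Cholesterol genes gave a list median near 0 between 10 and 20 weeks, but Ch25h, a low-expressed member, stood far above it in microglia-like cells. This gene, which makes 25-hydroxycholesterol, was higher at 20 weeks by a log2 ratio of 4.85 (3.89 to 6.28) in E2, 4.86 (3.75 to 6.63) in E3 and 4.14 (3.03 to 5.92) in E4, from 7, 5 and 5 UMIs at 10 weeks. It lies below the minimum of 20 CPM and was picked after its values had been seen.

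Of the 30 genes that met the size rule between E2 and E3, 9 (30%) lie within 20 Mb of Apoe, where 2.39% of the measured genes lie, a ratio of 12.6, as do 2 of the 4 between E4 and E3 and 1 of 17 with a position between E4 and E2. Across genes, which are not independent replicates, the 10- and 20-week ratios had r = 0.75 near Apoe and 0.11 elsewhere for E2 against E3, 0.36 and 0.19 for E4 against E3 (with 96 weeks, 0.29 and 0.060 from 10 weeks and 0.40 and −0.048 from 20 weeks), and −0.13 and 0.13 for E4 against E2. Sequence of the donor strain carried with the exchanged locus is a candidate explanation and would reach other cell types. There the 5 near genes measured had a median ratio of 0.066 in the direction seen in microglia-like cells, 3 of them in that direction. That median lies below the bound written beforehand. Of the genes that met the rule elsewhere, the 15 measured there had a median of 0.098, 9 of them in that direction. The near genes ranged from −0.77 for Pirb to 0.74 for Gmfg, and this spread, weighed afterwards, leaves the explanation open. The mix of these cell types differed between libraries too, neutrophil-like cells taking 0.887% of 10-week E2 and 2.41% of 10-week E3. Depth as the whole cause is argued against by the median UMIs, which differed by a log2 ratio of −0.00063 (−0.028 to 0.023) at 10 weeks. At 20 weeks that log2 ratio was 0.088 (0.049 to 0.12). With every cell thinned to 1000 UMIs the 9 near genes had a median smallest ratio of 0.73, against 0.70. Of them 6 met the rule and the others stood at 0.47 to 0.50. Ratios were already scaled by library totals, so thinning could hardly move them and does not test depth. The allele itself and a strain effect limited to microglia cannot be told apart here.

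The 55 genes that met the size rule as lower at 20 than at 10 weeks in microglia-like cells include Ddit4, Fkbp5, Per1 and Tsc22d3, which respond to glucocorticoids. These examples were picked after their values had been seen, and no list of glucocorticoid genes was measured. A different mix of states stays open as part of the lower values. In cells of homeostatic clusters the median log2 ratio of the 55 genes was −0.47 (quartiles −0.70 and −0.37), against −0.71 over all microglia-like cells. All 55 were still below 0 there, and 17 met the rule. A signal that reached the other cell types may be part of the lower values too, since the median of the 27 genes measured in T-cell-like cells was −0.41 (quartiles −0.59 and −0.11), with 22 lower. Per1 went the other way in T-cell-like (0.38, 0.043 to 0.72), B-cell-like (0.99, 0.59 to 1.42) and NK-cell-like cells (0.75, 0.19 to 1.33), which leaves this open. Age, run and handling of the pool cannot be told apart, as each age was 1 pool.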
